A study of Mus musculus with 12 samples.

How the data were processed

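The deposited gene counts of 12 libraries from mouse embryonic stem cells were analysed. Per the labels' protocols, cells were kept with LIF, or were taken through embryoid bodies for 3 days without LIF and then cultured for 6 days in 7.5% oxygen. RNA was bound to beads, reverse-transcribed with a template-switching oligonucleotide, amplified, tagmented and amplified again before sequencing. As described, this library type does not mark the strand of origin, and no molecular identifiers were described. Per the submitters' processing notes, the tools were bcl2fastq 2.16.0.10, TopHat2 2.0.12, HTSeq 0.6.1p1 and edgeR 3.10.0, with the mm10 genome. Trimming, alignment settings, the gene annotation and the strand setting of the counting were not given in the sources used here. Reads were not aligned again here.

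The count table held 23336 gene symbols, and the 5 summary lines that name no gene were set aside. Between 45.4% and 53.3% of each library's assigned and unassigned reads fell in no annotated gene, and 0.241% to 0.926% were ambiguous. Chromosomes and coordinates came from an annotation of the same genome, which placed 23108 symbols (99.0%), among them 1026 on the X chromosome. The genes Jpx and Ftx appeared under older symbols, as Enox and B230206F22Rik. Because strands were not separated as described, reads of antisense pairs such as Xist and Tsix or Igf2r and Airn could not be told apart where the genes overlap. Members of families with near-identical copies, such as Xlr3, Zscan4 and Usp17l5, carry the same doubt.

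Counts were modelled in R 4.3.3 with edgeR 4.0.16: 1 model of all 12 libraries with a mean for each of 6 groups of 2, TMM scaling, the default expression filter and the quasi-likelihood F test. Of the genes, 12814 were tested. Adjusted p means the Benjamini-Hochberg value over all tested genes of a comparison, and a gene was said to rise or fall when it was below 0.05. Fold changes are log2 values with the standard error derived from the edgeR test. The comparisons were the 3 pairs of lines within each state, the change on differentiation in each line, and the differences between lines in that change. With 2 libraries per group no other split of the samples can be tested, and the smallest exact permutation p of such a comparison is 0.33. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

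CPM are counts per 1e6 of TMM-scaled library size, given as mean ± SD over the 2 libraries of a group. Where a group held 0 counts of a gene, a fold is given as at least the value reached with 3 counts spread over the group. Where it held 1 to 3 counts, a ratio with a 95% interval is given. These intervals and floors cover counting error only, since amplification duplicates could not be removed.

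The X-linked shift is the median log2 fold change of 488 tested X-linked genes, with Xist and Tsix left out, minus the median of 12249 autosomal genes. It was tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the 12 comparisons, and again with the correlation estimated from the data.

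Named genes were picked by a rule set before the data were examined. Rlim, Xist, Tsix, Jpx and Ftx were always followed. In each comparison the 5 largest rises and 5 largest falls were taken, requiring a mean of at least 10 CPM in the higher group and no overlap of the libraries, and leaving out predicted genes and pseudogenes. Up to 4 X-linked genes each way were taken by the same rule, and from each fixed list up to 4 members with the smallest p. Among the genes the rule picked, those whose call held in all 12 fits that left out a single library were preferred in print, a preference set after values were seen. A gene that the rule picked between the undifferentiated female lines is not reported. Where another gene is printed, the text says that it was picked after values were seen.

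The 21 fixed lists, chosen before the data were examined, were these: X inactivation centre, genes reported to escape X inactivation, X-linked pluripotency and MAPK regulators, Y-linked genes, naive and general pluripotency, formative and primed pluripotency, primitive and visceral endoderm, mesoderm and cardiac, neuroectoderm, trophoblast, blood and endothelium, fibroblast and feeder cells, 2-cell-like state, imprinted genes, DNA methylation machinery, MAPK feedback, hypoxia response, X silencing factors, RLIM substrates and partners, p53 targets, and heat shock and handling stress. Each was tested with camera at the preset correlation, adjusted over the lists of a comparison, and again with an estimated correlation. The count of members called over all genes is given with the count called when p was adjusted over the list alone.

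Alternatives set before the data were examined were RLE size factors, TMM factors from autosomal genes, no filter, a stricter filter, the replicate number as a block, a model of only the libraries compared, each library left out in turn, DESeq2 1.42.0, a minimum absolute log2 fold change, the X-linked set without the escape list, the mean in place of the median, and an estimated correlation in camera. A pair of further alternatives was added after the data had been seen: the table without Rn45s and Lars2, whose counts hold reads derived from ribosomal RNA, and the table without differentiated RlimKO female replicate 1 and differentiated WT male replicate 2, the libraries with the highest and lowest share of Rn45s.

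In a self-test, counts were simulated without the measured differences between groups, and 100 genes were then changed at each fold size. The edgeR test recovered 47% of 2-fold and 94% of 4-fold changes in undifferentiated RlimKO against WT females, 51% and 97% in undifferentiated WT females against males, 57% and 98% in differentiated RlimKO against WT females, and 59% and 99% in differentiated WT females against males. All recovered genes had the right direction. False calls were 8 of 149, 10 of 158, 4 of 159 and 7 of 165. A simulated X-linked shift of 0.20 was returned as 0.183, 0.196, 0.216 and 0.199. The simulated libraries did not carry the wider spread of the differentiated male pair. That pair had a chi-square of 26.6 per degree of freedom, against 1.86 to 2.37 in the other pairs. The rates of recovery and of false calls therefore hold for libraries of even spread only. Recovery was not given separately for weakly expressed genes.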

Results

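Gene counts were examined from a female WT line (Pgk12.1), a female line labelled RlimKO and a male WT line (E14), each undifferentiated and differentiated, with 2 libraries per group. Libraries held 2011919 to 5401940 counts in genes. Rn45s, a ribosomal RNA precursor, took up much of this depth: 48.1 ± 2.53% (mean ± SD), 49.9 ± 8.29% and 47.1 ± 11.1% of the counts in undifferentiated WT female, RlimKO female and male libraries, and 40.4 ± 2.75%, 49.3 ± 26.1% and 14.4 ± 11.4% in the differentiated ones. Differentiated male replicate 2 stood lowest at 6.36%. In the deposited counts the name of this library also falls outside the numbered series of all the others, for a reason the labels do not give. The libraries of the differentiated male pair also differed most from each other (chi-square of 26.6 per degree of freedom, against 1.86 to 2.37 in the other 5 pairs). All 12 libraries share 1 estimate of spread. Leaving out either of these male libraries raised the number of genes called in every comparison between lines, and leaving out a library of any other group compared lowered it. Female and male cells were also different cell lines, so sex and line could not be separated. Each female genotype was likewise represented by a single line. An effect of the RlimKO label could therefore not be separated from other differences between the female lines. The labels give the strain C57BL/6 for every sample, which was not tested here, and a strain difference between the lines would bear on every comparison between them. Results below are edgeR log2 fold changes ± SE and adjusted p, n = 2 libraries per group, unless another test is named. Where a result is given without a library, only that library was left out of the model.

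Rlim, the X-linked gene of a ubiquitin ligase that acts on XCI in vivo, was examined first (coordinates X: 103957163 to 103981284). In undifferentiated libraries it stood at 267 and 282 CPM in WT females, 159.96 and 150.04 CPM in those labelled RlimKO, and 212 and 273 CPM in males. In differentiated libraries the values were 258 and 266, 290.1 and 299, and 267 and 275 CPM. Rlim was thus lower in the undifferentiated RlimKO-labelled libraries (fell by 0.82 ± 0.15 against WT females, adjusted p = 0.0437), but it was present there, and it was not lower after differentiation (0.17 ± 0.14, adjusted p = 0.654). The fall was not called in 10 of the 12 fits that left out a single library, with adjusted p up to 0.41. It was called in the 2 fits without a differentiated male library, and DESeq2 also called it (adjusted p = 0.000459). Counts summed over a gene cannot show which exons were transcribed, and the labels do not state the deleted part. The Y-linked genes Eif2s3y, Uty and Ddx3y had counts in the male libraries only, apart from 1 Eif2s3y count in undifferentiated RlimKO-labelled replicate 2.

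**Figure D1:**
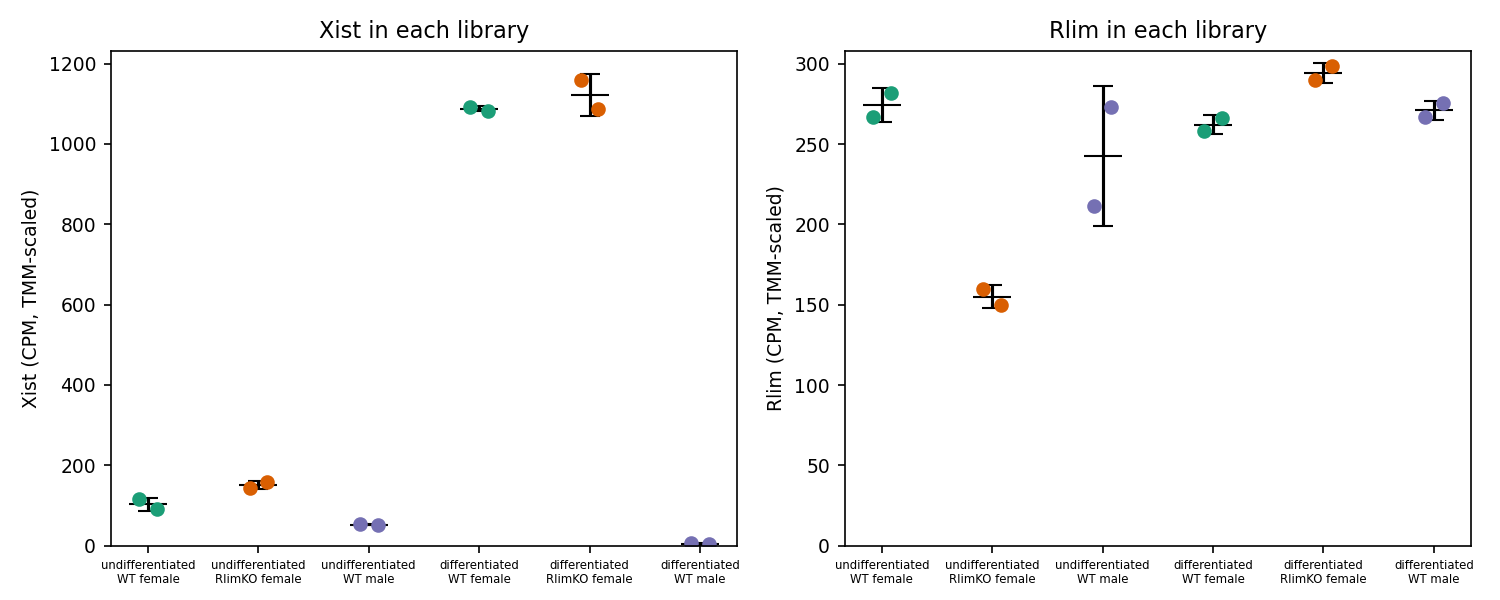
Xist (left) and Rlim (right) in each library, in CPM with TMM scaling; points are libraries, bars the mean ± SD. Xist reached 1087 and 1122 CPM in the differentiated female groups and 4.71 CPM in the males, while Rlim was lowest in the undifferentiated RlimKO-labelled group (155 CPM).

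Xist, the RNA that coats and silences the inactive X chromosome, rose on differentiation in both female lines and fell in the male line. Its mean went from 103 ± 16.3 to 1087 ± 6.15 CPM in WT females (log2 fold change 3.39 ± 0.19, adjusted p = 9.73e-09), from 151 ± 9.85 to 1122 ± 51.4 CPM in the RlimKO-labelled line (2.89 ± 0.19, adjusted p = 2.59e-08), and from 51.9 ± 1.71 to 4.71 ± 2.10 CPM in males (-3.57 ± 0.24, adjusted p = 2.46e-08). No difference in Xist between the female lines was called before (0.55 ± 0.19, adjusted p = 0.315) or after differentiation (0.05 ± 0.17, adjusted p = 0.946). Before differentiation the libraries did not overlap, with 144 and 158 CPM in the RlimKO-labelled line against 115 and 92.0 CPM in WT females. A difference there is thus not excluded. In differentiated cells Xist was higher than in males by 7.96 ± 0.25 (adjusted p = 8.79e-11) in WT females and by 8.001 ± 0.25 (adjusted p = 8.32e-11) in the RlimKO-labelled line. These calls held in all 12 fits that left out a library. Before differentiation the higher Xist of WT females (0.995 ± 0.19, adjusted p = 0.0083) was not called without undifferentiated WT female replicate 1 or either undifferentiated male library (adjusted p up to 0.084), whereas that of the RlimKO-labelled line was kept (1.55 ± 0.19, adjusted p = 0.00032). Reads of Xist and Tsix could not be separated where these genes overlap, which bears on the low counts of undifferentiated cells.

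Tsix, the antisense repressor of Xist, fell on differentiation in all 3 lines: by 3.05 ± 0.60 (adjusted p = 0.000772) in WT females, 3.04 ± 0.60 (adjusted p = 0.00075) in the RlimKO-labelled line and 3.63 ± 0.68 (adjusted p = 0.000446) in males. Ftx (listed as B230206F22Rik), a noncoding gene of the same centre that acts on Xist, rose on differentiation in the RlimKO-labelled line (1.27 ± 0.34, adjusted p = 0.00739, not called without undifferentiated replicate 2 or differentiated replicate 1 of that line, up to 0.114). Differentiated RlimKO-labelled cells also had more Ftx than males (1.42 ± 0.32, adjusted p = 0.011, but 0.124 without differentiated RlimKO-labelled replicate 1). Jpx, a noncoding activator of Xist, was not called in any comparison.

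X-linked genes were higher in undifferentiated females than in males and much less so after differentiation. The X-linked shift of undifferentiated cells was 0.90 (1.86-fold) in WT females (camera adjusted p = 3.21e-38; 0.00089 with an estimated correlation), and 86.7% of X-linked genes were positive against 41.5% of autosomal genes. In the RlimKO-labelled line it was 0.93 (1.91-fold, camera adjusted p = 1.7e-32; 0.00089 with an estimated correlation), with 83.4% against 40.6%. With genes of 0 counts at their bound, the shifts were 0.91 and 0.96. After differentiation the shift was 0.19 (1.14-fold) in either female line (camera adjusted p = 0.00293 in both), and the estimated correlation ended this call (adjusted p = 0.109 in both). At the bound these shifts were 0.20 and 0.18. Without differentiated male replicate 2 they were 0.102 (camera adjusted p = 0.214) for WT and 0.121 (camera adjusted p = 0.109) for the RlimKO-labelled line, and without replicate 1 they were 0.326 and 0.288. The mean gave 0.299 and 0.361 in place of the median. With no expression filter the RlimKO-labelled line stood at 0.0694 (camera adjusted p = 0.00262).

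**Figure D2:**
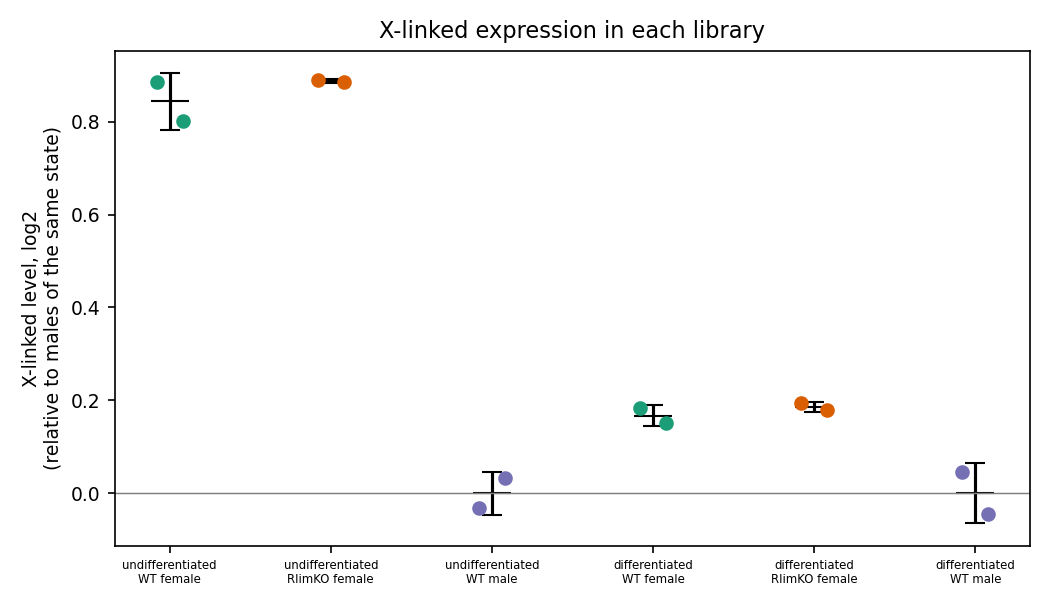
X-linked level of each library (log2 relative to the males of the same state); points are libraries, bars the mean ± SD. Undifferentiated females lay at 0.84 ± 0.061 (WT) and 0.89 ± 0.004 (RlimKO-labelled), differentiated females at 0.17 ± 0.022 and 0.19 ± 0.011.

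The female lines did not differ from each other in X-linked level, with a shift of 0.005 (camera adjusted p = 0.916) before and 0.01 (camera adjusted p = 0.861) after differentiation. Between single libraries of the lines the shift ran from -0.001 to 0.09 before and from -0.004 to 0.043 after. X-linked counts other than Xist and Tsix made up 5.36 ± 0.101% of the counts outside Rn45s and Lars2 in undifferentiated WT females, 5.22 ± 0.169% in the RlimKO-labelled line and 3.14 ± 0.0962% in males. After differentiation these shares were 3.83 ± 0.0561%, 3.72 ± 0.0714% and 3.44 ± 0.172%.

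Few genes (31) were called between undifferentiated RlimKO-labelled and WT females in the model of all 12 libraries. A model of only the libraries compared called these 31 and 272 others, so the low count depended on the model. Higher in the RlimKO-labelled line was Dpysl2, a regulator of axon growth (1.52 ± 0.21, adjusted p = 0.02; 55.6 ± 10.0 against 19.5 ± 0.790 CPM). Lower were Sp4, a transcription factor of the Sp family (1 against 41 counts, a ratio of 41.6 with interval 7.06 to 1682, adjusted p = 0.02), and Smc1b, a meiotic cohesin subunit (-2.19 ± 0.34, adjusted p = 0.02). None of these 3 was called when any undifferentiated female library was left out (adjusted p up to 0.327). Among X-linked genes, Klhl13, a ubiquitin ligase adaptor whose loss in female cells eases differentiation, fell from 264 ± 22.7 to 101 ± 17.1 CPM (-1.38 ± 0.25, adjusted p = 0.0437). Dnmt3l, a cofactor of DNA methylation, fell from 68.2 ± 7.35 to 14.1 ± 0.676 CPM (-2.27 ± 0.42, adjusted p = 0.0437), and Meg3, a maternally expressed noncoding RNA, rose (1.16 ± 0.19, adjusted p = 0.0321). The calls of Klhl13 and Dnmt3l held only in the 2 fits without a differentiated male library (adjusted p up to 0.41 in the others), and that of Meg3 was lost without any undifferentiated female library, undifferentiated male replicate 2 or either differentiated WT female library (up to 0.319). Meg3 lies in a stretch of chromosome 12 whose genes were raised together here (window medians of 0.370 and 0.566 between 101918901 and 112146208).

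In this comparison 31 genes were called by edgeR, 13 higher and 18 lower (X-linked 1 and 4), with 1289 at unadjusted p below 0.05. Without either library of the undifferentiated WT female or RlimKO-labelled pair no gene was called (0 in edgeR, with 947, 1183, 1025 and 976 at unadjusted p below 0.05, and 70 called by DESeq2 on all libraries). The count was 9 and 7 without undifferentiated male replicates 1 and 2, 6 and 6 without differentiated WT female replicates 1 and 2, 9 and 9 without the differentiated RlimKO-labelled ones, and 413 and 413 without the differentiated males. It also moved to 144 with no filter, to 303 in a model of these 4 libraries alone and to 412 without the libraries of extreme Rn45s share (differentiated RlimKO-labelled replicate 1 and male replicate 2 together, a choice made after the data were seen). Of the 16 named genes called here, 0 were kept in every fit (31 of 31 calls were kept without differentiated male replicate 1).

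Some lists shifted as a whole between the undifferentiated female lines although few members were called. Naive and general pluripotency genes were lower in the RlimKO-labelled line (median -0.30, camera adjusted p = 0.000266; 0.694 with an estimated correlation), with 0 of 24 called by edgeR (2 adjusted over the list alone, 7 at unadjusted p below 0.05, 0 by DESeq2). Genes of the 2-cell-like state were higher (median 2.20, camera adjusted p = 2.1e-05; 0.0839 with an estimated correlation), with 0 of 4 called by edgeR (3 over the list alone, 3 unadjusted, 0 by DESeq2). The p53 targets were lower (median -0.57, camera adjusted p = 0.00229; 0.694 with an estimated correlation), with 0 of 12 called by edgeR (3 over the list alone, 5 unadjusted, 0 by DESeq2). Hypoxia response genes were higher (median 0.18, camera adjusted p = 0.00722; 0.694 with an estimated correlation), with 0 of 22 called by edgeR (4 over the list alone, 5 unadjusted, 3 by DESeq2). DNA methylation machinery was lower (median -0.14, camera adjusted p = 0.0149; 0.258 with an estimated correlation), with Dnmt3l the only call among 11 genes. Maternally expressed Meg3 and Rian were the only calls among 23 imprinted genes, which did not shift (camera adjusted p = 0.724), and the X inactivation centre (1 of 14 called) had a negative median (-0.16) beside a positive mean (0.33; camera adjusted p = 0.928). Genes named as RLIM substrates and partners did not shift (camera adjusted p = 0.63), with 0 of 11 called by edgeR (0 over the list alone, 1 unadjusted, 0 by DESeq2).

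Undifferentiated WT females differed from males first in X-linked genes. Hprt, the purine salvage gene that a widely used E14 derivative lacks, had 601 counts against 2 (ratio 543, interval 150 to 4492, adjusted p = 2.8e-09). Xlr3c and Tex13, X-linked genes of germ cells, had 0 counts in males (at least 33.7-fold and 31.9-fold higher, adjusted p = 0.000806 for both). Escape genes were higher, among them Eif2s3x, a translation initiation factor (1.30 ± 0.16, adjusted p = 0.000476), and Kdm6a, a histone demethylase (1.06 ± 0.17, adjusted p = 0.00266). Tcl1, a kinase coactivator of naive cells, stood at 100.2 ± 13.3 against 32.8 ± 1.26 CPM (1.61 ± 0.20, adjusted p = 0.000535), in a window of chromosome 12 raised by 0.593. Lower in females were Lef1, a WNT-responsive transcription factor (-3.21 ± 0.38, adjusted p = 0.000341), Tagln, a smooth muscle actin binder (-3.18 ± 0.48, adjusted p = 0.00186), and Egln3, an oxygen sensor (-2.04 ± 0.29, adjusted p = 0.00105). All genes of this paragraph were called in all 12 fits that left out a library, as were 21 of 53 named calls.

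Of 849 genes called in that comparison, 400 were higher and 449 lower (X-linked 155 and 5). Calls fell to 183 and 232 without undifferentiated WT female replicates 1 and 2, to 167 and 220 without undifferentiated male replicates 1 and 2, and to 563 and 556 without differentiated WT female replicates 1 and 2. They went to 2282 and 2275 without differentiated male replicates 1 and 2, to 2016 in a model of these 4 libraries, to 2266 without the libraries of extreme Rn45s share and to 536 at a log2 fold change of at least 1. The higher share of 47.1% became 57.9% (480 and 349) without Rn45s and Lars2.

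Of the lists, 8 of 16 X-linked pluripotency and MAPK regulators were higher and none lower (11 over the list alone; camera adjusted p = 1.9e-10, and 0.0264 with an estimated correlation), but 1 was higher without undifferentiated WT female replicate 1 or undifferentiated male replicate 1. Of 13 genes reported to escape X inactivation, 6 were higher and 1 lower (10 over the list alone; camera adjusted p = 1.69e-06, and 0.0264 with an estimated correlation), with 2 higher without either of these libraries. In the X inactivation centre 4 of 14 were higher and 1 lower (6 over the list alone; camera adjusted p = 9.27e-06, and 0.0373 with an estimated correlation), with 2 higher without undifferentiated WT female replicate 1 or either undifferentiated male library. Formative and primed genes were lower (median -0.75, camera adjusted p = 0.00484; 0.0601 with an estimated correlation), with 2 of 11 called (1 without undifferentiated WT female replicate 1 or male replicate 1), and so were hypoxia response genes (camera adjusted p = 0.00765; 0.503 with an estimated correlation), with 4 of 22 lower and 1 higher (9 over the list alone; 1 lower without undifferentiated WT female replicate 1). The first 3 lists named here hold X-linked genes, which as a whole stood 0.90 above autosomal genes in this comparison. Their camera tests against all genes therefore do not show a shift particular to these lists. The 3 Y-linked genes were all lower. Blood and endothelium genes did not shift (camera adjusted p = 0.721), with 0 of 15 called by edgeR (0 over the list alone, 1 unadjusted, 0 by DESeq2), nor did heat shock and handling stress (camera adjusted p = 0.486), with 1 of 10 higher. Of 23 imprinted genes 3 were higher and 4 lower (13 over the list alone; camera adjusted p = 0.486), among them Grb10, a growth-limiting receptor adaptor (-1.40 ± 0.20, adjusted p = 0.00137). At the fewest 1 was higher, without undifferentiated male replicate 1, and 1 lower, without either undifferentiated WT female library or male replicate 2.

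The undifferentiated RlimKO-labelled line was set against the same male libraries, so agreement with WT females is no separate evidence. Hprt had 681 counts against 2 (ratio 606, interval 167 to 5017, adjusted p = 2.03e-09), and Nxf3, an X-linked RNA export factor, stood at 54.3 ± 3.27 against 0.592 ± 0.214 CPM (6.52 ± 0.44, adjusted p = 1.86e-06). Tcl1 was higher again (2.26 ± 0.20, adjusted p = 3.94e-05), as were the maternally expressed Meg3 (1.73 ± 0.19, adjusted p = 0.000132) and Rian (1.97 ± 0.24, adjusted p = 0.000272). These 3 genes lie in a stretch of chromosome 12 whose genes were raised together (window medians of 0.889 and 0.947 between 101918901 and 112146208). Gpc4, an X-linked heparan sulfate proteoglycan, was lower (-2.97 ± 0.43, adjusted p = 0.00088), as were Lamb1, a laminin of the endoderm basement membrane (-2.07 ± 0.29, adjusted p = 0.000745), and Gbp1, an interferon-induced GTPase with 0 counts in these females (at least 20.03-fold, adjusted p = 0.00083). These calls were kept in all 12 fits, as were 26 of 68 named genes called in this comparison. Dppa3, a protector of maternal methylation, was lower (-2.85 ± 0.54, adjusted p = 0.00476; 0.0593 without undifferentiated RlimKO-labelled replicate 1).

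Here 1282 genes were called, 589 higher and 693 lower (X-linked 168 and 8). The count became 557 and 310 without undifferentiated RlimKO-labelled replicates 1 and 2, 391 and 428 without undifferentiated male replicates 1 and 2, and 2803 and 2800 without differentiated male replicates 1 and 2. It moved to 2383 in a model of these 4 libraries, to 2817 without the libraries of extreme Rn45s share and to 801 at a log2 fold change of at least 1. The higher share of 45.9% became 57.7% without Rn45s and Lars2 (755 and 553). Of the 2-cell-like state 3 of 4 genes were higher (4 over the list alone; median 2.98, camera adjusted p = 0.000169, and 0.0401 with an estimated correlation), among them Zscan4c (24 against 2 counts, ratio 21.4, interval 5.31 to 187, adjusted p = 0.0313), but 0 were called when any of the 4 libraries of this comparison was left out (edgeR; 4 of 4 at unadjusted p below 0.05 and 0 by DESeq2 on all libraries). X-linked pluripotency and MAPK regulators were higher again, 9 of 16 with 1 lower (12 over the list alone, camera adjusted p = 2.55e-08, and 0.0401 with an estimated correlation). Most of the higher calls were lost without undifferentiated male replicate 2. X-linked genes as a whole stood 0.93 above autosomal ones here, so this test does not show a shift particular to the list.

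Differentiation changed 6238 genes in WT females (3393 higher, 2845 lower), 6157 in the RlimKO-labelled line (3386 and 2771) and 6922 in males (3672 and 3250). Without Rn45s and Lars2 the split of the RlimKO-labelled line turned to 3040 higher and 3099 lower. Pou5f1, the core pluripotency factor, fell by 4.02 ± 0.21 (adjusted p = 4.18e-09), 5.13 ± 0.24 (adjusted p = 1.77e-09) and 5.26 ± 0.22 (adjusted p = 5.31e-10). Col4a1, a basement membrane collagen of endoderm, rose by 6.17 ± 0.20 (adjusted p = 1.78e-10), 5.83 ± 0.21 (adjusted p = 3.57e-10) and 4.83 ± 0.19 (adjusted p = 2.8e-10). Of genes tested, 2299 were higher and 1802 lower in all 3 lines, where 257 and 156 would be met if the lines were independent, and 67 moved in opposite directions. Almost all named genes kept their call in every fit (87 of 91, 90 of 96 and 87 of 90). X-linked genes fell against autosomes in the female lines, by 0.56 in WT (0.678-fold, camera adjusted p = 0.000413; 0.0885 with an estimated correlation) and by 0.48 in the RlimKO-labelled line (0.715-fold, camera adjusted p = 0.000858; 0.0935 with an estimated correlation). With no filter these values were -0.229 and -0.237 (camera adjusted p = 0.00262 and 0.00544). In males the shift was 0.21 (camera adjusted p = 0.375), with 0.0469 without differentiated male replicate 1 and 0.346 without replicate 2.

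Of 24 pluripotency genes 23 fell in WT females, 21 in the RlimKO-labelled line and 23 in males (24, 22 and 23 over the list alone; camera adjusted p = 2.2e-16, 1.89e-14 and 3.74e-13, but 0.143, 0.103 and 0.131 with an estimated correlation). Primitive and visceral endoderm genes rose, 19, 17 and 20 of 21 (camera adjusted p = 1.06e-09, 8.72e-07 and 4.97e-09; 0.0437, 0.0998 and 0.0558 with an estimated correlation). Apob, a lipoprotein of visceral endoderm, rose by 8.20 ± 0.30, 5.64 ± 0.28 and 6.26 ± 0.22. Mesoderm and cardiac genes rose, 15, 11 and 16 of 17 with 1 lower in the RlimKO-labelled line (camera adjusted p = 1.87e-05, 0.0022 and 5.35e-06; 0.0437, 0.0998 and 0.0397 with an estimated correlation). Fibroblast and feeder genes rose, 13, 11 and 13 of 14 with 1 lower in males (camera adjusted p = 9.38e-05, 0.000145 and 0.000607; 0.258, 0.24 and 0.353 with an estimated correlation). With genes of 0 counts at their bound, the list medians were 4.79, 3.20 and 4.95 for endoderm, 4.45, 3.28 and 4.93 for mesoderm, and 5.98, 6.36 and 5.68 for fibroblast genes. Neuroectoderm genes rose in 3 and fell in 7 of 10 cases in each line, with Sox11, a factor of neural progenitors, up by 4.12 ± 0.25, 1.84 ± 0.21 and 2.62 ± 0.20.

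Imprinted genes rose on differentiation, 19, 20 and 19 of 23, with 2 lower in each female line (1 in WT without undifferentiated or differentiated replicate 1; camera adjusted p = 1.19e-07, 1.09e-07 and 5.95e-08; 0.234, 0.224 and 0.249 with an estimated correlation). DNA methylation genes mostly fell, 8, 7 and 8 of 11 with 3 higher in each line (camera adjusted p = 0.00177, 0.00599 and 0.00422; 0.092, 0.0998 and 0.106 with an estimated correlation). Among them Tet1, a methylcytosine dioxygenase, fell by 3.13 ± 0.14, 3.55 ± 0.15 and 3.80 ± 0.15. Hypoxia response genes rose in 16 of 22 cases in WT females (18 over the list alone; camera adjusted p = 7.09e-06, and 0.143 with an estimated correlation). In the RlimKO-labelled line 9 rose and 2 fell (camera adjusted p = 0.0648), and in males 10 rose and 5 fell, with 2 falls at the fewest over the fits (camera adjusted p = 0.0877). Among 26 X silencing factors 13, 8 and 13 fell and 5, 4 and 4 rose (camera adjusted p = 0.043, 0.136 and 0.0251; 0.143, 0.24 and 0.131 with an estimated correlation). At the fewest 8 fell in WT females (without differentiated replicate 2), 3 in the RlimKO-labelled line (without differentiated replicate 2) and 7 in males (without undifferentiated replicate 2). Of those factors, Jarid2, a partner of Polycomb, fell by 1.70 ± 0.15, 1.70 ± 0.15 and 1.73 ± 0.14. Zfp42, the RLIM substrate that represses Xist, fell by 3.99 ± 0.26, 4.77 ± 0.29 and 4.84 ± 0.27. All genes of this paragraph and of the preceding one were kept in all 12 fits.

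Differentiated RlimKO-labelled and WT females differed in single genes of several kinds. Apob was lower in the RlimKO-labelled line (112 ± 1.19 against 304 ± 17.9 CPM, -1.44 ± 0.16, adjusted p = 0.000344), as were Bgn, an X-linked matrix proteoglycan (-3.54 ± 0.38, adjusted p = 0.000402), Cyp1b1, a cytochrome of mesenchyme (-4.31 ± 0.46, adjusted p = 0.000308), and the imprinted Grb10, a receptor adaptor that limits growth (-2.70 ± 0.31, adjusted p = 0.000424). Zim1, a maternally expressed zinc finger gene, stood at 4.26 ± 2.24 against 78.4 ± 0.0780 CPM (-4.36 ± 0.32, adjusted p = 7.53e-06). Rps6ka6, an X-linked kinase of the MAPK pathway, was higher (123 ± 13.2 against 38.5 ± 1.09 CPM, 1.68 ± 0.21, adjusted p = 0.000776). These 6 were the only ones of 44 named calls that were kept in every fit. Upk1b, a uroplakin of epithelium (2.85 ± 0.34, adjusted p = 0.00105), was not called without differentiated RlimKO-labelled replicate 2 (adjusted p = 0.0517). Hand1, a factor of trophoblast and cardiac mesoderm, was higher (1.73 ± 0.25, adjusted p = 0.00292) but not called without differentiated WT female replicate 1 or that library (up to 0.0695).

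Here 332 genes were called, 134 higher and 198 lower (X-linked 5 and 9). Calls fell to 50 and 70 without differentiated WT female replicates 1 and 2, and to 52 and 12 without differentiated RlimKO-labelled replicates 1 and 2. They went to 1680 and 1672 without differentiated male replicates 1 and 2, to 779 with no filter, to 2154 in a model of these 4 libraries and to 1152 without the libraries of extreme Rn45s share. Genes between 79526424 and the end of chromosome 10 held 36 of the 134 higher calls.

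Pluripotency genes were lower in the differentiated RlimKO-labelled line, 7 of 24 with none higher (15 over the list alone; camera adjusted p = 1.14e-08, and 0.215 with an estimated correlation). None was called without differentiated RlimKO-labelled replicate 2 (0 in edgeR, against 17 at unadjusted p below 0.05 and 7 by DESeq2 on all libraries). Endoderm genes were lower, 6 of 21 with 1 higher (9 over the list alone; median -0.99, camera adjusted p = 1.46e-09, and 0.0434 with an estimated correlation), with 1 lower without that library. Mesoderm and cardiac genes were lower, 3 of 17 with 1 higher (9 over the list alone; median -0.79, camera adjusted p = 0.000454, and 0.0434 with an estimated correlation). Trophoblast genes were higher, 3 of 12 (6 over the list alone; median 0.89, camera adjusted p = 1.75e-05, and 0.0434 with an estimated correlation). For mesoderm 0 lower calls were left by edgeR without differentiated WT female replicate 1 or either RlimKO-labelled library (9 at unadjusted p below 0.05 and 5 by DESeq2 on all libraries). For trophoblast 0 were left without differentiated WT female replicate 1 or RlimKO-labelled replicate 2 (6 and 3). Hypoxia response genes were lower (4 of 22, 1 higher, 13 over the list alone; camera adjusted p = 9.37e-05, and 0.215 with an estimated correlation), with 0 lower by edgeR without differentiated WT female replicate 1 or either RlimKO-labelled library (14 unadjusted, 7 by DESeq2), as were p53 targets (0 of 12 called by edgeR, 6 over the list alone, 7 unadjusted, 3 by DESeq2; camera adjusted p = 2.73e-05, and 0.331 with an estimated correlation). MAPK feedback genes were lower (1 of 14, 6 over the list alone; camera adjusted p = 0.00206, and 0.215 with an estimated correlation).

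Differentiated WT females differed from males in several imprinted genes. Igf2r, a maternally expressed receptor that clears IGF2, stood at 66.9 ± 3.61 against 1864 ± 343 CPM (-4.80 ± 0.18, adjusted p = 3.86e-10), and Grb10 at 26.1 ± 2.38 against 855 ± 277 CPM (-5.03 ± 0.23, adjusted p = 4.52e-09). H19, a maternally expressed noncoding RNA, stood at 6548 ± 425 against 147 ± 23.2 CPM (5.48 ± 0.43, adjusted p = 4.75e-06), and Plagl1, a paternally expressed zinc finger gene, at 1109 ± 94.4 against 46.1 ± 35.8 CPM (4.64 ± 0.44, adjusted p = 4.25e-05). Hprt was higher (5.99 ± 0.31, adjusted p = 3.28e-08), as were Dkc1, an X-linked telomerase component (1.60 ± 0.16, adjusted p = 6.51e-05), Tdgf1, a Nodal coreceptor of pluripotent cells (2.59 ± 0.24, adjusted p = 2.85e-05), and Tet1 (1.43 ± 0.14, adjusted p = 5.26e-05). Slc2a1, a glucose transporter (-1.30 ± 0.14, adjusted p = 0.000133), and Hand1 (-1.92 ± 0.25, adjusted p = 0.000563) were lower. All of these were kept in the 12 fits that left out a library, as were 28 of 51 named calls. Those fits pooled the spread of all groups. A model of these 4 libraries alone kept 5 of the 1149 calls, so not all genes named here were called in it.

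**Figure D3:**
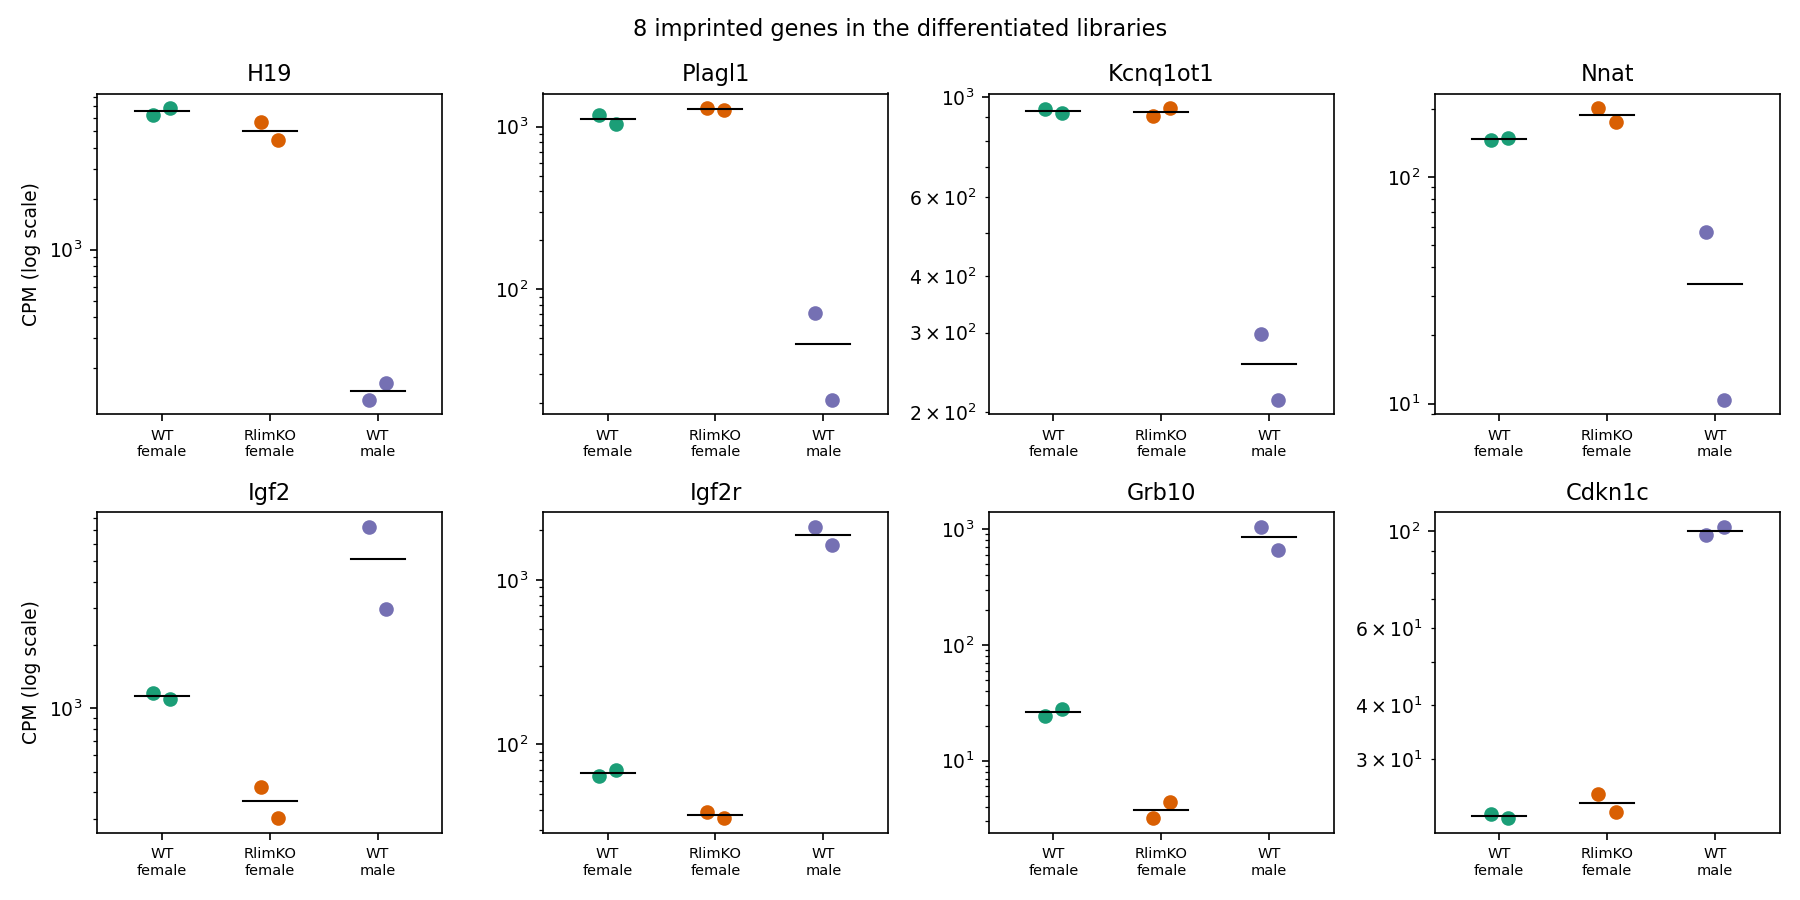
CPM (log axis) of 8 imprinted genes in each library; points are libraries, lines group means. In differentiated cells Igf2r stood at 66.9 and 37.2 CPM in WT and RlimKO-labelled females against 1864 CPM in males, and H19 at 6548 and 5028 against 147 CPM.

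In that comparison 1149 genes were called, 599 higher and 550 lower (X-linked 49 and 17). Calls fell to 233 and 186 without differentiated WT female replicates 1 and 2 and went to 4391 and 2185 without differentiated male replicates 1 and 2. A model of these 4 libraries alone called 5 genes, and the count was 2109 without the libraries of extreme Rn45s share and 660 at a log2 fold change of at least 1. Of 23 imprinted genes 10 were higher and 7 lower (20 over the list alone; camera adjusted p = 0.0452, and 0.718 with an estimated correlation), with 5 higher and 3 lower at the fewest, without differentiated WT female replicate 1 or 2. Pluripotency genes were higher in 9 of 24 cases (17 over the list alone; camera adjusted p = 0.000721, and 0.489 with an estimated correlation), with 5 without differentiated WT female replicate 1. Trophoblast genes were lower in 5 of 12 cases (8 over the list alone; median -1.18, camera adjusted p = 0.000199, and 0.0664 with an estimated correlation), and mesoderm genes in 5 of 17 (8 over the list alone; median -0.75, camera adjusted p = 0.0183, and 0.153 with an estimated correlation), each with 1 left without either differentiated WT female library. Fibroblast genes were higher (median 0.94, camera adjusted p = 0.00326; 0.489 with an estimated correlation), with 1 of 14 called. This was 0 by edgeR without differentiated WT female replicate 1 (4 unadjusted and 1 by DESeq2 on all libraries). Genes reported to escape X inactivation did not shift (camera adjusted p = 0.113), with 2 of 13 higher and 1 lower (5 over the list alone). The 2 higher were not called without either differentiated WT female library or undifferentiated male replicate 2 (0 by edgeR; 5 unadjusted and 3 by DESeq2 on all libraries).

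The differentiated RlimKO-labelled line, set against the same male libraries as WT females, also differed from males in imprinted genes, with Grb10 at 3.79 ± 0.850 against 855 ± 277 CPM (-7.73 ± 0.29, adjusted p = 3.04e-10), Igf2r (-5.65 ± 0.19, adjusted p = 9.54e-11) and H19 (5.10 ± 0.42, adjusted p = 8.49e-06). Sp4 had 0 counts against 148 (at least 21.6-fold lower, adjusted p = 0.000202). Lower were Afp, a fetal serum protein of visceral endoderm (-3.80 ± 0.47, adjusted p = 0.000452), and the cardiac muscle genes Myl7 (-4.66 ± 0.69, adjusted p = 0.000942) and Actc1 (-3.37 ± 0.42, adjusted p = 0.000489). Hmgn5, an X-linked nucleosome binder, was higher (2.39 ± 0.36, adjusted p = 0.000942). These were kept in the 12 fits that left out a library, which pooled the spread of all groups, as were 22 of 58 named calls. Of 1489 genes called, 724 were higher and 765 lower (X-linked 48 and 13). Calls fell to 469 and 272 without differentiated RlimKO-labelled replicates 1 and 2 and went to 4530 and 2484 without differentiated male replicates 1 and 2. The model of these 4 libraries called 10 genes, and 882 passed at a log2 fold change of at least 1.

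Mesoderm and cardiac genes were lower in that comparison, 10 of 17 (12 over the list alone; median -1.75, camera adjusted p = 2.08e-05, and 0.0474 with an estimated correlation), with 2 without differentiated RlimKO-labelled replicate 2. Endoderm genes were lower in 9 of 21 cases (13 over the list alone; median -1.01, camera adjusted p = 5.07e-06, and 0.0919 with an estimated correlation), with 3 without that library. Imprinted genes were higher in 10 and lower in 5 of 23 cases (17 over the list alone; camera adjusted p = 0.00081, and 0.553 with an estimated correlation). MAPK feedback genes were lower in 4 of 14 cases (9 over the list alone; camera adjusted p = 0.00101, and 0.219 with an estimated correlation). None of the 4 was called without either differentiated RlimKO-labelled library (0 in edgeR, against 9 at unadjusted p below 0.05 and 2 by DESeq2 on all libraries).

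The change of X-linked genes on differentiation differed between each female line and males, by -0.76 for WT (camera adjusted p = 3.72e-17; 0.00375 with an estimated correlation) and -0.73 for the RlimKO-labelled line (camera adjusted p = 7.76e-15; 0.00447 with an estimated correlation), and did not differ between the female lines (-0.05, camera adjusted p = 0.916). The difference between lines in the change of Xist was 6.96 ± 0.31 (WT against male, adjusted p = 1.04e-08), 6.46 ± 0.30 (RlimKO-labelled against male, adjusted p = 1.34e-08) and -0.50 ± 0.25 (RlimKO-labelled against WT, adjusted p = 0.548).

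Whole autosomes or parts of them also differed between the lines. Genes of chromosome 8 were higher in females than in males, with a median of 0.36 (WT) and 0.40 (RlimKO-labelled) above the autosomal median in undifferentiated and 0.35 and 0.44 in differentiated cells (685 genes). Chromosome 12 (477 genes) was higher in the same comparisons by 0.18 and 0.42, then 0.38 and 0.43, and between the female lines by 0.22 in undifferentiated and 0.05 in differentiated cells. It was the most shifted autosome in undifferentiated RlimKO-labelled cells and in differentiated WT females against males. Its windows were raised from 65062424 on, up to 1.11 and 1.34 at 109611822 to 112146208 in differentiated WT and RlimKO-labelled cells against males. The window of Tcl1, Meg3 and Rian (101918901 to 109611500) was raised by 0.901 and 0.891 there. Distal windows of chromosome 5 were raised by 0.153 to 0.359 between the undifferentiated female lines from 108461232 on, and stood at -0.0641 to 0.171 between the differentiated ones. Against males the same windows stood at -0.0871 to 0.2004 (WT) and 0.114 to 0.568 (RlimKO-labelled) in undifferentiated, and at 0.0285 to 0.462 and -0.0757 to 0.460 in differentiated cells. Other windows also stood apart in females against males. A window of chromosome 6 (58584523 to 81910562) was raised by 0.857 (WT) and 0.655 (RlimKO-labelled) in undifferentiated and 0.798 and 0.524 in differentiated cells. The next window (81957851 to 86438374) was raised by 0.248 and 0.314, then 0.615 and 0.565. On chromosome 13 a window (21513221 to 23933773) was raised by 0.249 and 0.294, then 1.25 and 1.80. That last shift was far larger in differentiated cells, where Rn45s averaged 14.4% of male counts against 40.4% and 49.3% in females. A difference of library content or cell mix was not separated there from one between the lines. Genes of the distal part of chromosome 10 were higher in the RlimKO-labelled line than in WT females, by 0.585 before and 0.540 (1.45-fold) after differentiation (320 genes), while those of the proximal part stood at -0.03 in both states (287 genes). No autosome shifted as far as the X-linked genes in undifferentiated cells, whereas in differentiated cells 2 (WT) and 5 (RlimKO-labelled) of 19 did. The boundary on chromosome 10 was placed from the undifferentiated libraries after their values had been seen.

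**Figure D4:**
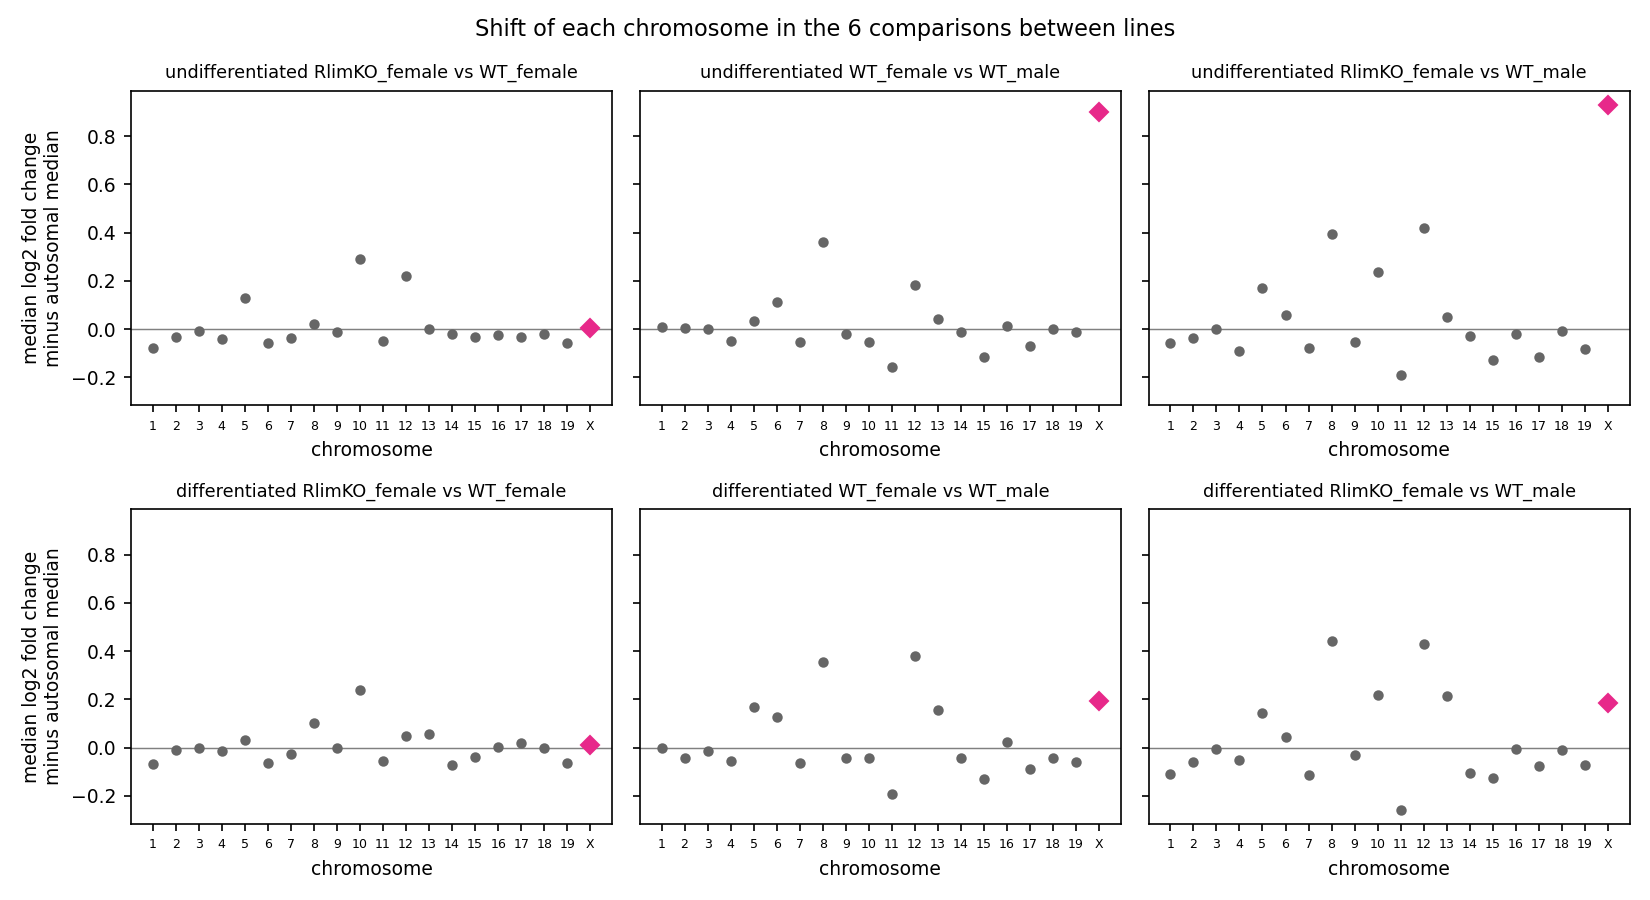
Median log2 fold change of each chromosome's genes minus the autosomal median, for 6 comparisons (diamond, X chromosome). The X chromosome lay far above the autosomes in undifferentiated females against males (0.90 and 0.93) and among them in differentiated cells (0.19 in both).

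**Figure D5:**
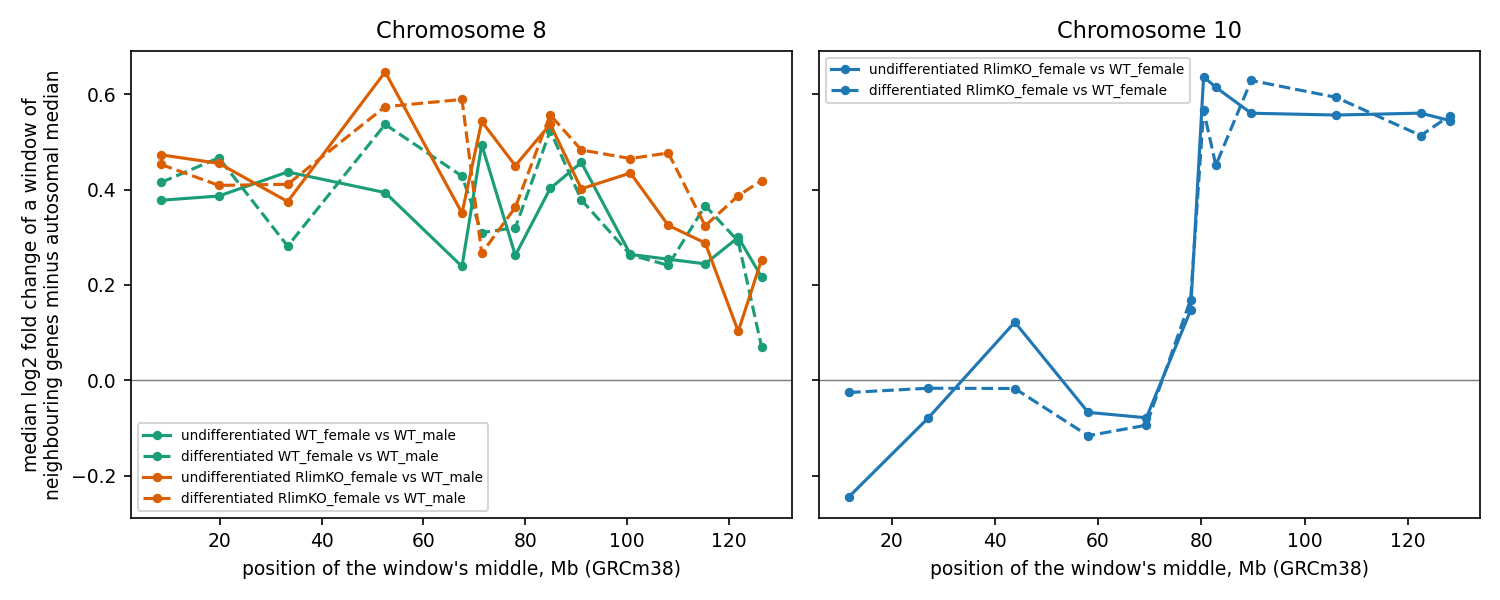
Median log2 fold change in windows of neighbouring genes against position (Mb) on chromosomes 8 (females against males) and 10 (RlimKO-labelled against WT females). Chromosome 8 was raised along its length, and chromosome 10 only in its distal part (0.585 and 0.540).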

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

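Chosen only after the result was seen were the tests of undifferentiated cells left in the cultures, of differences between cell lines on any chromosome, of the role of differentiated male replicate 2, of copy number on chromosomes 8 and 10, and of the imprinted clusters, including that of a different mix of cell types.

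Several results were picked out because the lines differed in how they changed on differentiation. The X-linked shift changed by -0.76 in WT females against males and by -0.73 in the RlimKO-labelled line against males. The change of Xist differed by 6.96 and 6.46 in the same pairs. The number of genes whose change differed was 26 between the female lines, 178 between WT females and males and 334 between the RlimKO-labelled line and males. These counts were not stable: with 1 library left out they ranged from 2 to 485, from 13 to 1886 and from 54 to 2016. In addition, data on which nothing was reported were picked out: 53.3% of the reads of differentiated male replicate 1 fell in no annotated gene, the highest share of the 12 libraries. What these reads hold was not analysed here.

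X-linked genes stood above those of males by 0.19 in both differentiated female lines, a call lost with an estimated correlation (adjusted p = 0.109 in both). Undifferentiated cells left in the cultures could raise X-linked genes. If such cells made up the whole excess, in proportion to the pluripotency genes, the female lines would differ by -0.0989. The measured difference was 0.00951, which argues against that case only. A smaller contribution was not tested. The pluripotency genes may also not measure the share of such cells. They were lower in the RlimKO-labelled line before differentiation too (median -0.30). Differences between cell lines on any chromosome could also raise X-linked genes. At least as far, up or down, shifted 2 autosomes in WT females and 5 of 19 in the RlimKO-labelled line, which met the prediction. But chromosomes 8 and 12, among those counted, had already been seen to be raised when the test was chosen. Its outcome was thus known beforehand and does not decide the cause of the X-linked excess. A role of differentiated male replicate 2 could not be decided, since without it the shift was 0.102 in WT females (camera adjusted p = 0.214) and 0.121 in the RlimKO-labelled line (camera adjusted p = 0.109) and no longer called. Incomplete silencing or escape in females would leave an excess of the same sign and was not tested against these.

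Runs of neighbouring genes on chromosomes 8 and 10 shifted together between the lines. A gain of chromosome 8 is often met in mouse embryonic stem cells. A copy-number difference of it would raise both the proximal and the distal part in every comparison of a female line with males. The lowest of 8 such values was 0.296, which fits. But the chromosome was picked because it was shifted, and both female lines were set against the same male libraries. The 8 values are thus not separate support. The highest was 0.477, below 0.585, the log2 ratio of 3 copies to 2. For chromosome 10, a difference of the whole chromosome was excluded (lowest value -0.00935), whereas one of the distal part fits, since the differentiated libraries gave 0.540 at a boundary drawn from the undifferentiated ones. With GC content and length of the longest annotated transcript regressed out, the shifts remained at 0.369 or more on chromosome 8. On chromosome 10 as a whole they remained at 0.234 or more. This argues against GC content and length as the cause in the form modelled only, and the distal part of chromosome 10 was not tested alone. Copy number itself could be shown only in DNA, which was not analysed here, and the raised stretches of chromosomes 5, 6, 12 and 13 were not tested for a cause.

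Imprinted genes stood apart between differentiated females and males. Loss of methylation at imprinting control regions has been reported in female lines with a pair of active X chromosomes. It predicts a direction for each of 12 imprinted clusters. In WT females 12 went that way (exact sign test p = 0.000488 against even chances, n = 12 clusters), so it fits. Without the Meg3-Dlk1 cluster, which lies in the raised stretch of chromosome 12, 11 of 11 did (exact sign test p = 0.000977). The clusters come from 1 pair of lines, so these p-values do not cover differences between lines. Only the difference between the lines was measured, so an opposite change in the male line would give the same signs. Methylation was not measured here. The RlimKO-labelled line gave the same counts, but against the same male libraries, so its agreement is no separate evidence and may come in part from them. Single genes went against the prediction: Peg10 (-0.28) and Dlk1 (0.95) in WT females, and Phlda2 (0.16) in the RlimKO-labelled line. Differentiated male replicate 2 was excluded as the sole source of these signs, since against replicate 1 alone 12 clusters still went the predicted way. Only signs were counted, and Mest stood at just 0.0124 there in the RlimKO-labelled line. A part of replicate 2 in the size of the differences was thus not excluded. A different mix of cell types could not be ruled out: in undifferentiated cells, where the same mix is not present, 9 of 12 clusters went the predicted way in WT females (exact sign test p = 0.146) and 7 in the RlimKO-labelled line (p = 0.774).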

How the results depend on the processing

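Besides the alternatives set beforehand, a pair was chosen only after the data had been seen: leaving out Rn45s and Lars2, and leaving out the libraries of highest and lowest Rn45s share. Where a value below changed, the cause was not tested, except that fits of fewer libraries hold fewer samples and a minimum fold change admits fewer genes by construction.

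The X-linked shift kept its side of the threshold in 142 of 144 fits that left out a library, and its direction wherever it was called. It did so under both other scalings, both other filters, the replicate block and the set without escape genes as well. In differentiated WT females against males it ranged from 0.102 to 0.326 over these fits, and in the RlimKO-labelled line from 0.121 to 0.288. Without the libraries of extreme Rn45s share it was 0.103 (camera adjusted p = 0.194) and 0.122 (camera adjusted p = 0.122). With an estimated correlation 4 calls were lost, at values that do not change: 0.195 and 0.186 in differentiated females against males, and -0.560 and -0.485 for differentiation of WT and RlimKO-labelled cells.

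Counts of genes called moved more. Over the fits that left out a library they ranged from 0 to 413 between the undifferentiated female lines (edgeR; 947 to 2030 at unadjusted p below 0.05), 167 to 2282 and 310 to 2803 in undifferentiated WT and RlimKO-labelled females against males, 12 to 1680 between the differentiated female lines, and 186 to 4391 and 272 to 4530 in differentiated females against males. For differences in change they ranged from 2 to 485 between the female lines and from 13 to 1886 and 54 to 2016 against males. Counts for differentiation itself stayed within 4303 to 7856.

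With no filter, calls numbered 144 between undifferentiated and 779 between differentiated female lines, and 200, 558 and 713 for the differences in change. A model of only the libraries compared gave 303, 2016 and 2383 in undifferentiated cells, 2154, 5 and 10 in differentiated cells, and 530, 23 and 39 for the differences in change, in the order RlimKO-labelled against WT, WT against male, RlimKO-labelled against male. Without the libraries of extreme Rn45s share these were 412, 2266 and 2817, then 1152, 2109 and 1919, then 404, 1232 and 1311. Of the calls against males in differentiated cells, 923 of 1149 and 984 of 1489 were kept there. DESeq2 called 70 genes between undifferentiated female lines and 56 for the difference in change. A log2 fold change of at least 1 left 536 and 801 calls in undifferentiated, and 660 and 882 in differentiated females against males.

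The camera test of 1 list and the values of a pair of genes changed direction. Blood and endothelium genes were lower in differentiated WT females (-1.14, camera adjusted p = 3.79e-08) and RlimKO-labelled cells (-1.22, camera adjusted p = 6.9e-07) than in males without the libraries of extreme Rn45s share. With all libraries their medians were already negative (-0.41 and -0.51), while the camera direction was up and not called (adjusted p = 0.162 and 0.184), so there the test changed its direction and the median did not. With the replicate block the median of the RlimKO-labelled line was 0.14 and not called (camera adjusted p = 0.359). Without differentiated male replicate 1, Hba-x, an embryonic globin gene, was higher in differentiated WT females than in males (3.83, adjusted p = 4.47e-09), and so was Pecam1, an endothelial adhesion gene (0.86, adjusted p = 0.00896). Without differentiated male replicate 2 both were lower (-2.82 and -1.59), and neither was called with all libraries (adjusted p = 0.308 and 0.376).

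Replicate numbers did not pair samples: correlations between groups of the differences between replicates ran from -0.0663 to 0.103. The replicate block moved no count of calls by more than 1.5-fold. Scaling changed the split of calls: in the difference in change between WT females and males, the higher share of 63.5% became 52.4% without Rn45s and Lars2 (88 and 80), and for the RlimKO-labelled line 58.1% became 46.5% with RLE (141 and 162) and 40.3% without Rn45s and Lars2 (127 and 188). Depth limited low genes. With the floor set at 3 counts, 0 counts in a group did not exclude levels up to 0.750 CPM in undifferentiated WT females, or up to 0.220 CPM in differentiated males.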

Other observations

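The differences in change below came from planned comparisons, but the genes of this part, Lars2 included, were picked only after values had been seen.

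Lars2, a mitochondrial leucyl-tRNA synthetase gene whose counts hold reads from ribosomal RNA, made up 7.22% and 4.82% of the counts in undifferentiated male replicates 1 and 2 but 0.862% and 0.0212% in the differentiated ones. In the female libraries it ranged from 2.71% to 7.84%. The share of Rn45s was also lowest in the differentiated males, at 22.5% and 6.36%.

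Differences between lines in the change on differentiation included imprinted genes that did not stand apart beforehand to the same extent. Between WT females and males these were H19 (5.82) and Igf2r (-4.23), and between the RlimKO-labelled line and males 6.46 and -5.22 for the same genes (edgeR log2 differences, n = 2 libraries per group). Grb10 also differed between the female lines (-2.64, adjusted p = 0.0145).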
